A study of Mus musculus with 2 samples.

How the data were processed

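Chromatin from the neural tube of mouse embryos at embryonic day 15.5 was immunoprecipitated with an antibody against acetylated lysine 9 of histone H3 (H3K9ac, a mark of active promoters and enhancers) and sequenced. Per the labels, the tissue came from the B6NCrl strain, embryos of both sexes were pooled, and there was 1 group of 2 biological replicates. Replicate 1 was a pool of 78 embryos and replicate 2 a pool of 62 embryos. Each library therefore averaged many animals, and the spread between the replicates is a spread between pools.

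The authors deposited 4 peak lists on the mm10 build, without column headers. Per the notes deposited with them, 1 list was called on each replicate against its own control and 1 on both replicates pooled against both controls, and the replicated list was derived from those 3 lists. The peak caller, its thresholds, the aligner and the read counts are not given in the sources used here, so the depth of each library is unknown and no interval that needs read counts was made. Each peak of the deposited lists carries a signal value, which is the authors' own strength of the peak against the control. Signals were used to describe and rank peaks within a list, and to compare gene groups and chromosomes within a list. They were also correlated between the lists of the replicates. The deposited lists also carry a display score per peak, which was not analysed, and a −log10 p and a −log10 q per peak. The smallest −log10 p was 2.02 in replicate 1 and 2.03 in replicate 2, and 30.4% and 28.4% of their peaks had a −log10 q under 2, so the lists of single replicates reach far into weak enrichment. All 32307 replicated peaks were found with unchanged position and signal in the pooled list.

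Peaks on chromosomes 1 to 19 and X were kept. This removed 22 of 59876 peaks of replicate 1, 13 of 54478 of replicate 2, 18 of 68044 pooled peaks and 14 of 32307 replicated peaks. Genes and transcripts were taken from GENCODE release M21 on the same build, which gave 21755 protein-coding genes with 93196 start sites. A peak was a promoter peak when it lay within 1000 bp of any protein-coding start site, and otherwise an exon, intron or intergenic peak. A gene's promoter signal was the highest signal of its promoter peaks. Replicated peaks up to 1000 bp apart were joined into domains, and a gene's breadth was the width of the widest domain at its start sites. A promoter was CpG-rich when the observed over expected CpG ratio within 500 bp of the gene's 5′ end was 0.6 or more in the reference sequence. Neighbouring genes that share a promoter or a domain share its value.

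Peaks of the replicates were compared by overlap of at least 1 bp and set beside 100 random placements of the same peaks on the same chromosomes. Shares of peak classes were set beside 10 such placements, and midpoints of distal peaks beside 100 placements of the same widths over 10000 bp from coding start sites. The overlap count of replicate 1 was checked with bedtools 2.31.1. Spearman's correlation of signal was taken across overlapping peaks and describes the lists, because peaks are not independent replicates. Gene lists were fixed before the data were examined: 26 lists of neural, regional, surrounding-tissue, housekeeping and sensory receptor genes, whose symbols all matched the annotation. Each list's share of genes with a replicated promoter peak was compared with all other protein-coding genes by a two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 26 lists with a threshold of 0.05. The odds ratio had 0.5 added to each cell. A list's median percentile of promoter signal, and of breadth, among genes with a promoter peak was set beside 10000 random lists of the same size, where at least 3 members had a peak, and adjusted over those lists. These p-values treat genes as independent and describe these peak lists; they do not measure variation between animals. With 1 group, no test of conditions was possible.

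The named genes followed a rule set before the data were examined. Per list, it took the 3 members with the highest promoter signal and, in list order, up to 4 members without a replicated promoter peak. Over all genes it took the 10 with the highest promoter signal and the 10 with the broadest domain. It also took the 5 strongest peaks of each replicate without an overlapping peak in the other and the 10 strongest replicated peaks over 10000 bp from any protein-coding start site, each with the nearest protein-coding gene. Other members are named where a count or contrast is described, and were chosen after their values were seen.

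On simulated data, the overlap step found the right partner for 1500 of 1500 peaks, and the promoter step found all 13936 planted promoter peaks among 21755 genes. For the promoter share test with 26 lists of 15 genes, 0 of 200 lists drawn at the background share of 65% were called. At a true share of 20%, 131 of 200 lists were called, and at 95%, 9 of 200 were. In these runs a single list of the 26 differed from the background, which makes the adjustment stricter than where many lists differ. The rates therefore do not carry over to the data, where progenitor and radial glia genes, with a peak at all 15, passed the threshold (adjusted exact p = 0.0046, Fisher's exact test). For the rank test, on 14000 simulated genes, 10 of 200 random lists had an unadjusted p under 0.05, as did 199 of 200 lists drawn from the low end of the ranks.

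The alternatives fixed beforehand were an overlap of at least 50% of the shorter peak, a −log10 p of 5 or more, equal numbers of top peaks, windows of 500 and 2500 bp, the pooled list, each replicate alone, 1 start site per gene, CpG-rich promoters only, a background without receptor genes, −log10 p in place of signal, and no joining or joining up to 3000 bp. The comparisons of chromosomes and of Hox groups and the start sites of noncoding genes were not planned. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.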

Results

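H3K9ac was mapped in the neural tube of mouse embryos at embryonic day 15.5, in 2 biological replicates pooled from 78 and 62 embryos. The design has 1 group, so it asks where the mark lay in this tissue and how far the replicates shared it. On the main chromosomes, replicate 1 had 59854 peaks with a median width of 285 bp, and replicate 2 had 54465 with a median of 310 bp. The authors' replicated list held 32293 peaks with a median width of 745 bp, which covered 33.3 Mb or 1.26% of these chromosomes. Of them 83.0% overlapped a peak in both replicates' own lists, 8.29% a peak of replicate 1 only, 7.33% of replicate 2 only and 1.38% of neither, so the list's name does not mean a called peak in both. Signals are the authors' peak values and read counts were not given, so the depth behind each peak is unknown.

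The first comparison was between the replicates. The strongest promoter peaks were found in both. Srsf6, which encodes a splicing factor, had the highest promoter signal of the replicated list (31.2, with 19.9 in replicate 1 and 27.0 in replicate 2; chromosome 2, 162930501 to 162933062). The next were Zc3h4 (29.5), Actb (28.2, a cytoskeletal actin), Mex3b (28.2), Mat2a (28.1, which makes the methyl donor S-adenosylmethionine), Atxn2l (27.2), Fam171a2 (26.7), Kmt5b (26.7, a histone H4 methyltransferase), Plcg1 (26.7) and Actg1 (26.4, the other cytoskeletal actin). In each replicate's own list these 10 genes had signals of 19.07 or more, while the median peak stood at 3.28 in both lists. Of 21755 protein-coding genes, 13968 had a promoter peak in both replicates, 402 in replicate 1 only, 344 in replicate 2 only and 7041 in neither.

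Counted by peaks, 31397 peaks of replicate 1 (52.5%, Wilson 95% interval 52.1 to 52.9) overlapped a peak of replicate 2, and 31495 of replicate 2 (57.8%, 57.4 to 58.2) overlapped a peak of replicate 1. The Wilson intervals treat peaks as independent and do not measure variation between pools. Random placement gave 2.38% and 2.59%. The overlapping peaks held 80.1% and 82.9% of the base pairs of their lists. All peaks in the strongest 2 deciles by p overlapped in both directions, against 18.9% and 21.3% in the weakest decile. Across the 31397 pairs, signals correlated with a Spearman's rho of 0.746 (95% interval 0.740 to 0.751, over peaks that are not independent), and across genes with a promoter peak in both replicates with a rho of 0.794.

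**Figure D1:**
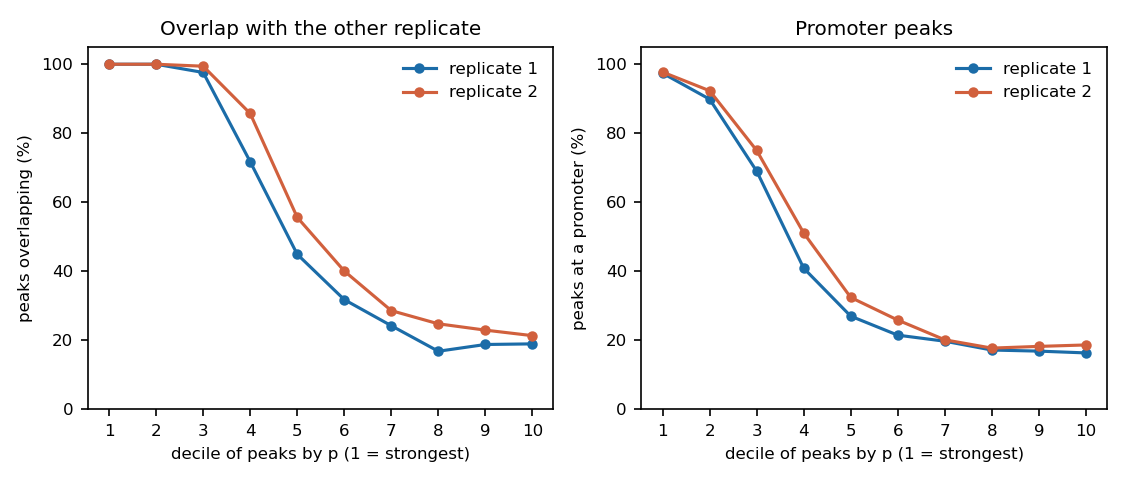
Percent of each replicate's peaks that overlap a peak of the other replicate (left) and percent that lie at a promoter (right), by decile of the list ordered by the authors' p from the strongest (1) to the weakest (10). Overlap falls from 100% to 16.8% in decile 8 of replicate 1, with 18.9% in decile 10. In replicate 2 it falls from 100% to 21.3% in decile 10.

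The peaks without a partner, 28457 in replicate 1 and 22970 in replicate 2, were weak and narrow. Their median signal was 2.81 and 2.74, against 5.22 and 5.07 for overlapping peaks, and their median width 208 and 215 bp, against 621 and 626 bp. Promoters held 14.9% and 16.0% of them, against 65.7% and 66.0% of overlapping peaks, and introns held 45.4% and 44.8%. In replicate 1 the strongest lay at the promoters of Sirt1 (a deacetylase; signal 7.38, chromosome 10, 63381373 to 63381915), Frg1 (7.02), Ppm1n (6.55) and Stard3 (6.43), and in an intergenic region 83048 bp from Slc38a4 (6.55). In replicate 2 they lay at the promoter of Lypd6 (6.33, chromosome 2, 50065993 to 50066349), in an intron of Zfp229 (5.70), and in intergenic regions whose nearest genes were Smad2 (6.28), Tbcb (5.70) and Tmem17 (5.62). Most of these promoters were not private to 1 pool: Sirt1 (14.0 and 10.2), Frg1 (8.74 and 8.10), Stard3 (10.7 and 7.39) and Lypd6 (9.18 and 7.18) had a stronger promoter peak in both replicates, and the unshared peak lay beside it. Ppm1n had none in replicate 2. Of the peaks with a −log10 p of 5 or more, 7565 and 6207 had no partner of any p in the other replicate. With 2 pools, no test separates a difference between pools from sampling.

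The second question was where in the genome the mark lay. Promoters held 19236 replicated peaks (59.6%, against 5.67% for random placement), introns 17.2% (29.4% at random), exons 5.14% (6.65%) and intergenic sequence 18.1% (58.2%). Promoter peaks had a median signal of 8.72 and intron peaks of 3.04. The promoter share rests on the list used: it was 41.5% in replicate 1, 44.9% in replicate 2 and 36.9% in the pooled list, which hold more weak peaks. By genes, 14051 (64.6%) had a replicated promoter peak, with 66.1% and 65.8% in the replicates. Of 10077 genes with a CpG-rich promoter 97.0% had a peak, and of the 11678 others 36.6%.

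Chromosome X, a comparison that was not planned, stood apart from the autosomes. The median promoter signal of its genes was 6.83, against 11.0 (chromosome 13) to 12.2 (chromosome 8) on the 19 autosomes. The share of its non-receptor genes with a promoter peak was 48.6%, against 55.3% to 78.7%. Among genes with a CpG-rich promoter the gap was smaller, with a replicated promoter peak at 91.0% on X and 97.2% on the autosomes. Chromosome X had 4.73 replicated peaks per Mb, against 8.65 to 22.8. Among all genes with a promoter peak, the ratio of the X median to the autosomal median was 0.630 in replicate 1 (95% bootstrap interval over genes 0.609 to 0.670) and 0.617 in replicate 2 (0.589 to 0.638). Intervals over genes cover the genes sampled and not variation between animals.

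**Figure D2:**
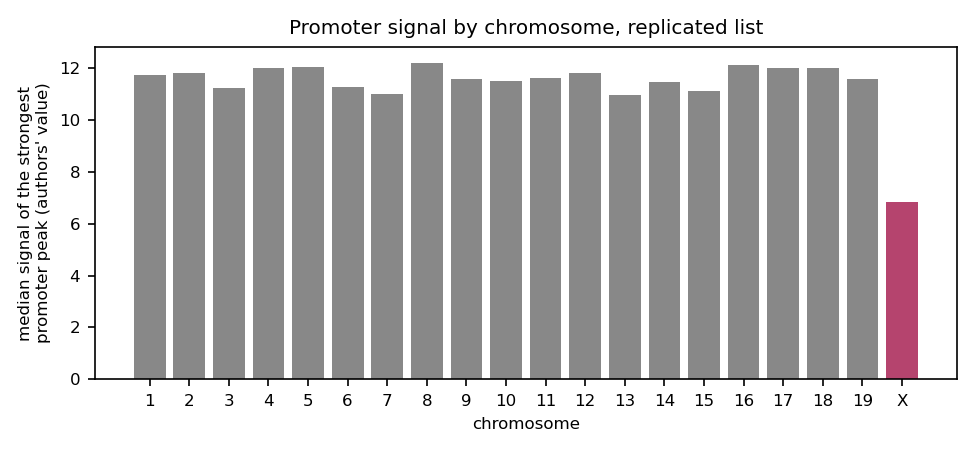
Median signal (the authors' value) of the strongest promoter peak over protein-coding genes with one, per chromosome, in the replicated list. Chromosome X stands at 6.83 and the autosomes between 11.0 and 12.2.

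The third comparison set gene lists against all other protein-coding genes. Of the 26 lists, 6 had a promoter peak more often than the other genes (64.6% of which had one), and 7 less often. All 16 pan-neuronal genes had a peak (adjusted exact p = 0.0040, Fisher's exact test), led by Ncam1 (an adhesion molecule; signal 22.1 in the replicated list, 17.2 in replicate 1, 18.8 in replicate 2), Elavl3 (18.1, an RNA-binding protein of neurons) and Tubb3 (17.6, a neuronal tubulin). All 15 progenitor and radial glia genes did too (adjusted exact p = 0.0046), led by Msi1 (17.2, with 21.8 and 11.6 in the replicates), Id4 (15.3) and Hes5 (12.4, an effector of Notch signalling; its peak is shared with Pank4). So did all 15 cell cycle genes (adjusted exact p = 0.0046; Aurka 15.8, Birc5 12.9, Mcm2 10.7), all 16 housekeeping genes (adjusted exact p = 0.0040; Actb 28.2, Ubc 24.5, Rpl13a 19.8), all 12 Hox genes of groups 1 to 4 (adjusted exact p = 0.023) and all 15 of groups 5 to 9 (adjusted exact p = 0.0046). The same members had a peak in each replicate's own list. None of these 6 lists stood above the background when lists and background were limited to CpG-rich promoters (adjusted exact p = 1), where 97.0% of genes have a peak and little room is left.

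The 7 lists with fewer promoter peaks than the other genes held forebrain and midbrain factors, genes of some non-neural tissues, germ cell genes and sensory receptor genes. Few muscle (14.3%), hepatocyte (6.25%), microglia (0%) and receptor genes (0.068%) had CpG-rich promoters, and these lists were not tested within that class. Of genes without such a promoter 36.6% had a peak, so all other genes are a high background for these lists. Within CpG-rich promoters the forebrain (log2 odds ratio -6.92), cardiac (-6.26) and germ cell lists (-5.89) stayed below (adjusted exact p = 3.4e-15, 0.00054 and 0.00012). In that class few genes were left, with a peak at 3 of 15 forebrain, 1 of 4 cardiac and 2 of 6 germ cell genes. Of 22 forebrain and midbrain transcription factors, 5 had a peak (22.7%, adjusted exact p = 0.00048). The highest were Satb2 (4.66), Hesx1 (3.92) and Emx1 (3.16), and Foxg1, Emx2, Otx1 and Otx2 had none in either replicate. The list had 9 genes with a peak in replicate 1 and 8 in replicate 2. Of 14 skeletal muscle genes 3 had one (adjusted exact p = 0.0040; Actn2 7.72, Ckm 4.13 at a peak shared with Klc3, Myod1 3.40), with none at Myf5, Myf6, Myog and Myh3 in the replicated list. Aif1 (2.66) was the single one of 14 microglia and leukocyte genes (adjusted exact p = 0.00017), without Ptprc, Csf1r, Cx3cr1 or C1qa. The list had 3 genes with a peak in replicate 1, where Cx3cr1 had a weak one (2.57), and 1 in replicate 2. Of 16 hepatocyte genes 2 had a peak (adjusted exact p = 0.00023), Foxa3 (14.3) and Apoh (12.2). Both share that peak with another gene, Sympk and Prkca, and Alb, Afp, Ttr and Apoa1 had none. This list had 4 genes in replicate 1, with a weak peak at Apoa1 (2.67), and 2 in replicate 2. Of 15 cardiac genes 4 had one (adjusted exact p = 0.0099, but 0.090 with the list of replicate 1 alone), among them Ryr2 (15.2), Tnni3 (3.92) and Myl2 (3.36). Nkx2-5, Tnnt2, Myh6 and Myh7 had none in the replicated list. The cardiac list had 6 genes with a peak in replicate 1 and 5 in replicate 2. Of 14 pluripotency and germ cell genes 2 had one (adjusted exact p = 0.00083; Dazl 5.31, Utf1 2.91), without Pou5f1, Nanog, Zfp42 or Dppa3, with 1 in replicate 1 and 3 in replicate 2. Only 3 of 1464 olfactory and vomeronasal receptor genes had a peak (0.205%; the p was too small to be held as a number), Vmn1r4 (11.9, shared with Nt5c3), Olfr94 (7.37) and Olfr1414 (2.66). Olfr1414 had no peak in either replicate's own list; each of those lists had 5 receptor genes with a peak.

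The remaining 13 lists did not differ from the other genes in this test, and genes named as having none lacked a peak in the replicated list. Among neural lists, a peak was found at 15 of 21 progenitor domain transcription factors, the factors that pattern the dorsoventral axis (adjusted exact p = 0.77; Ascl1 12.3, Irx3 8.48, Prdm8 6.29; none at Nkx2-9, Nkx6-2, Dbx1 and Pax7). It was found at 19 of 27 postmitotic interneuron factors (adjusted exact p = 0.78; Lbx1 9.29, Gbx1 8.98, Lmx1b 8.98; none at Tlx1, Evx1, Evx2 and Vsx2). The interneuron list had 22 genes with a peak in each replicate's own list and 23 in the pooled list. Within CpG-rich promoters the progenitor domain and interneuron lists both fell below the background in the replicated list (adjusted exact p = 0.00078 and 0.00031). Motor neuron genes had 12 of 14 (adjusted exact p = 0.28; Foxp1 14.5, Ret 9.87, Etv4 6.96; none at Isl2 and Lhx3), and 0.017 with the pooled list. Neurotransmitter genes had 12 of 16 (0.64; the transporters Slc6a1 14.5 and Slc6a9 14.0, and Gad1 7.97; none at Slc17a8, Th, Tph2 and Dbh). Floor and roof plate genes had 9 of 12 (0.72; Zic1 11.51, shared with Zic4, Spon1 9.74, Shh 8.19; none at Foxa2, Wnt1 and Wnt3a), and Hox genes of groups 10 to 13 had 9 of 12 (0.72).

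Of these 13, the glial and surrounding-tissue lists had a peak at 35.7% (erythroid) to 78.6% (astrocyte lineage) of their genes. Astrocyte lineage genes had a peak at 11 of 14 (adjusted exact p = 0.62; Nfib 15.3, Glul 14.4 shared with Teddm2, Slc1a2 13.2; none at Aqp4, Gfap and S100b). Oligodendrocyte lineage genes had one at 8 of 13 (adjusted exact p = 0.82), with Mbp 12.02, Sox8 6.65 and Cnp 6.08. None was at Cspg4, Plp1, Mag and Mog. The Mbp peak lay at the 5′ end of a gene with 12 start sites, so it need not mark every Mbp start. Dorsal root ganglion and neural crest genes had 9 of 15 (0.82; Mpz 12.2, whose peak is shared with Sdhc, Ngfr 7.84, Scn9a 6.04; none at Runx3, Prdm12, Scn10a and Trpv1). Cartilage and mesenchyme genes had 11 of 17 (1; Runx2 9.44, Sox9 8.48, Twist1 6.32; none at Matn1, Col9a1, Pax1 and Pax9), and meningeal and pericyte genes 11 of 15 (0.74, and 0.047 with the pooled list; Zic1, Notch3 8.25, Vtn 6.14; none at Foxd1, Slc6a13, Rgs5 and Cspg4). Endothelial genes had 7 of 14 (0.44; Egfl7 9.23 shared with Gm20532, Kdr 5.56, Erg 4.81; none at Cdh5, Pecam1, Tek and Tie1). Erythroid genes had 5 of 14 (0.084; Tfrc 14.96, an iron uptake receptor of many dividing cells, Klf1 6.96, Gypa 3.90; none at Gata1, Hbb-bt, Hbb-bs and Hba-a1). That list passed the threshold with either replicate alone, with adjusted p of 0.044 and 0.045.

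**Figure D3:**
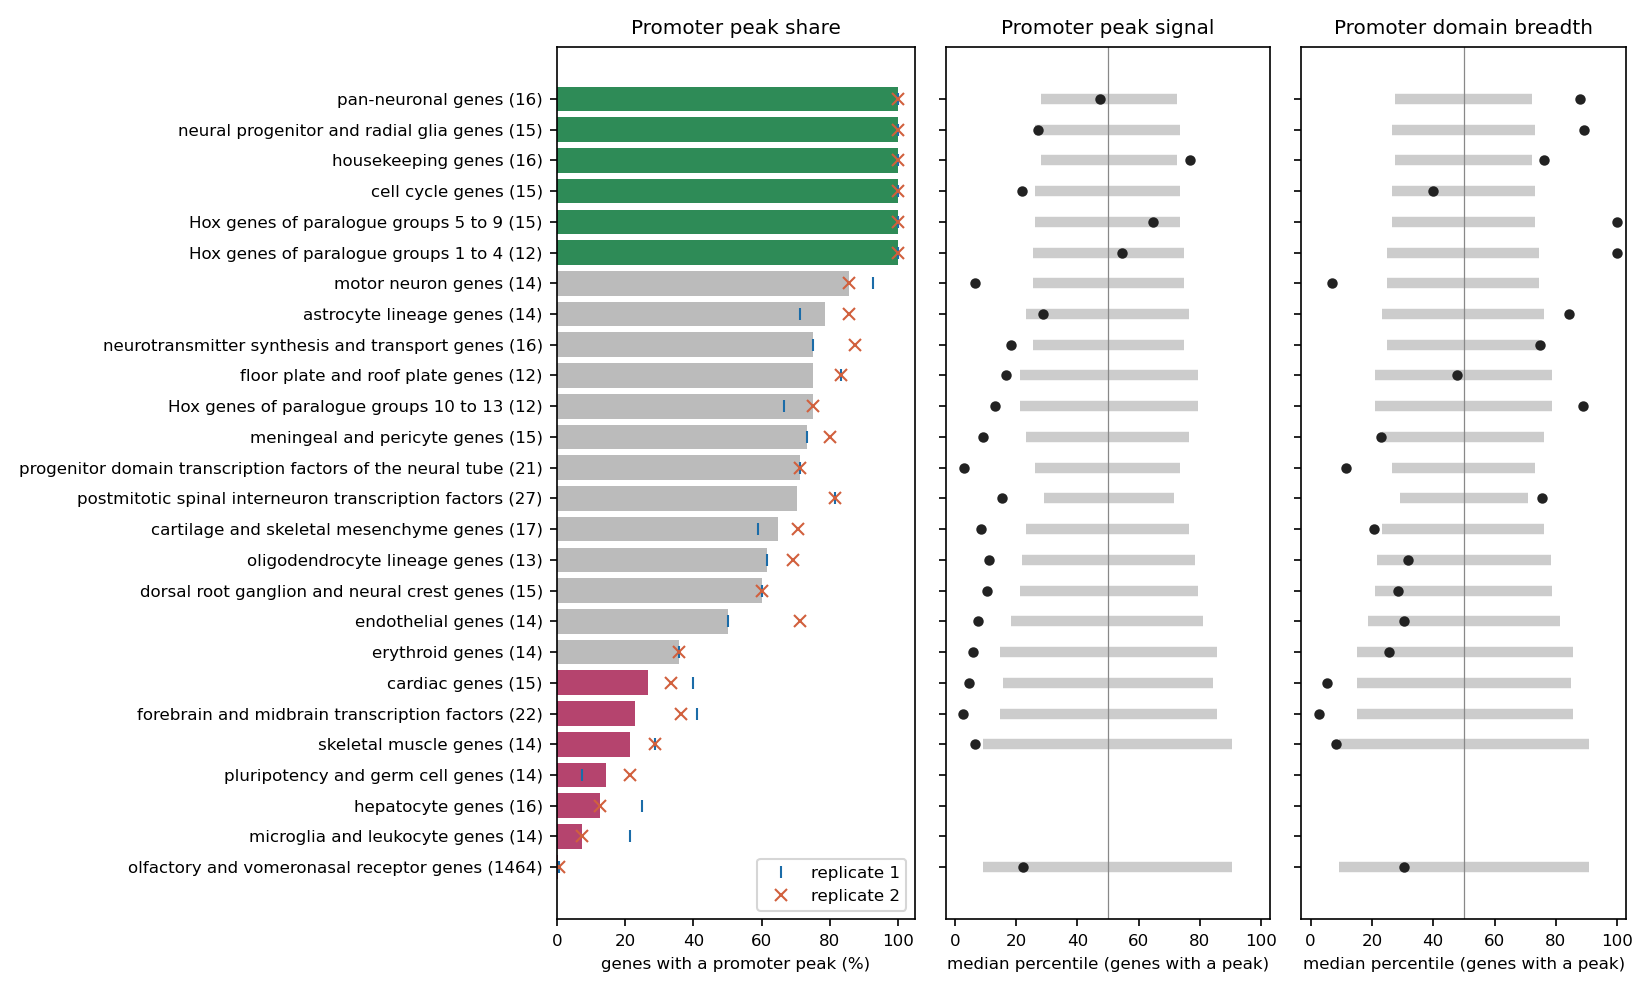
Left, percent of each list's genes (number in parentheses) with a replicated promoter peak as bars (green above, dark pink below and grey not different from the other genes at an adjusted p of 0.05), with replicate 1 and replicate 2 as symbols; middle and right, the list's median percentile of promoter signal and of domain breadth (points) with the range of 95% of random lists of the same size (grey). Pan-neuronal, progenitor and Hox lists of groups 1 to 9 reach 100% and lie at 87.8 or higher in breadth, while progenitor domain factors lie at 3.03 in signal.

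Neural lists differed from random lists in signal, breadth or both, and were not tested against each other here. Pan-neuronal genes were near the middle in signal (median percentile 47.3) and broad (87.8, adjusted permutation p = 0.00092 against random lists), with domains of 6228 bp at Elavl4, 5679 bp at Tubb3 and 5261 bp at Rbfox3. Progenitor and radial glia genes had a median percentile of 27.2 in signal (adjusted permutation p = 0.081) and 89.2 in breadth (0.00092), with 6629 bp at Hes5 and 5895 bp at Id4, against a median of 1964 bp over all genes with a promoter peak; the adjusted p of the breadth was 0.078 with replicate 1 alone and 0.058 without joining. Astrocyte lineage genes were broad as well (84.3, adjusted permutation p = 0.017, and 0.095 with replicate 2 alone), with 17784 bp at Nfib. Progenitor domain factors were low in both, with a median percentile of 3.03 in signal (adjusted permutation p = 0.0023; 5.9 in replicate 1 and 6.2 in replicate 2) and 11.7 in breadth (0.0031). Motor neuron genes were at 6.6 (0.0023) and 7.1 (0.00092). Postmitotic interneuron factors were low in signal (15.3, adjusted permutation p = 0.0028) while their breadth was at 75.6 (0.033), with 18813 bp at Lhx1, 17862 bp at Lmx1b and 17128 bp at Lhx5. That breadth fell to 47.2 without joining of nearby peaks and was 45.6 with replicate 2 alone and 52.7 with replicate 1 alone. Neurotransmitter genes were at 18.2 in signal (0.012) and 74.9 in breadth (0.066), with 10902 bp at the vesicular transporter gene Slc32a1.

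In signal, housekeeping genes were above random lists (76.8, adjusted permutation p = 0.023; 55.1 and 0.79 within CpG-rich promoters), and 16 lists were below, of the 23 with enough genes with a peak. Cell cycle genes were among those below, at 21.9 (0.024), and the forebrain and midbrain factors at 2.5 (0.0028). With −log10 p in place of signal, Hox genes of groups 5 to 9 were above as well (78.5, 0.020). In breadth, 8 lists were above random lists and 4 below. Housekeeping genes were among those above (76.3, 0.038), though not without joining of nearby peaks (61.2, 0.39) or within CpG-rich promoters (47.5, 0.86). Each of these p-values rests on 10000 random lists, which can give no unadjusted p under 0.0002.

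The Hox genes, which encode positional identity along the body axis, carried the broadest domains of the genome. The broadest spanned 86463 bp over Hoxb2, Hoxb3, Hoxb4, Hoxb5, Hoxb6, Hoxb7, Hoxb8 and Hoxb9 (chromosome 11, 96268950 to 96355412), and the next 40419 bp over part of the Hoxa cluster (chromosome 6, 52200096 to 52240514), with start sites of Hoxa3, Hoxa5, Hoxa6, Hoxa7, Hoxa9, Hoxa10 and the overlapping gene model Gm28308. The median percentile of breadth was 99.8 for groups 1 to 4 and 99.9 for groups 5 to 9 (adjusted permutation p = 0.00092 for both), over 8 and 7 separate domains, and 88.9 for groups 10 to 13 (0.0066), where the median without joining was 35.6. Replicated peaks covered 59.7% of the span of the Hoxa cluster, 51.8% of Hoxb, 52.7% of Hoxc and 49.9% of Hoxd, with 53.3%, 50.4%, 43.2% and 42.4% in replicate 1 and 56.3%, 49.7%, 45.7% and 42.8% in replicate 2.

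Promoter signal was lower for groups 10 to 13, at the 5′ end of the clusters. This contrast was chosen after the values were seen. With genes without a peak set to 0, the median replicated signal was 12.03 for groups 1 to 4, 13.3 for groups 5 to 9 and 4.45 for groups 10 to 13. Groups 5 to 9 were above groups 10 to 13 (permutation p = 0.00072, 2-sided; 6.0e-05 in replicate 1 and 0.00012 in replicate 2), and so were groups 1 to 4 (0.0018; 0.0024 and 0.010). Groups 1 to 4 and 5 to 9 did not differ in this test (0.46). Neighbours that share a peak make these p-values too small. A gene's signal was the highest over all its annotated start sites, some of which lie beside other groups. The Hoxa3 peak overlaps Hoxa7, and Hoxc5 took its value from the peak of Hoxc10. The contrast therefore compares gene models rather than positions along the clusters. Among the highest were Hoxa3 (19.9; its peak at chromosome 6, 52210535 to 52215513, lies at an alternative start site shared with Gm28308), Hoxd3 and Hoxd4 (both 18.3, at 1 shared peak), Hoxb9 (17.2), Hoxa7 (15.9) and Hoxd8 (15.7, with 20.6 and 7.80 in the replicates). In groups 10 to 13, Hoxc10 reached 9.23, Hoxa10 8.72 and Hoxc11 7.34, while Hoxd12, Hoxa13 and Hoxd13 had no peak in either replicate. At the 3′ end, Hoxb1 had 2.53, while the replicated peak was 12.5 at the start of Hoxa1 and 4.91 at the start of Hoxd1.

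**Figure D4:**
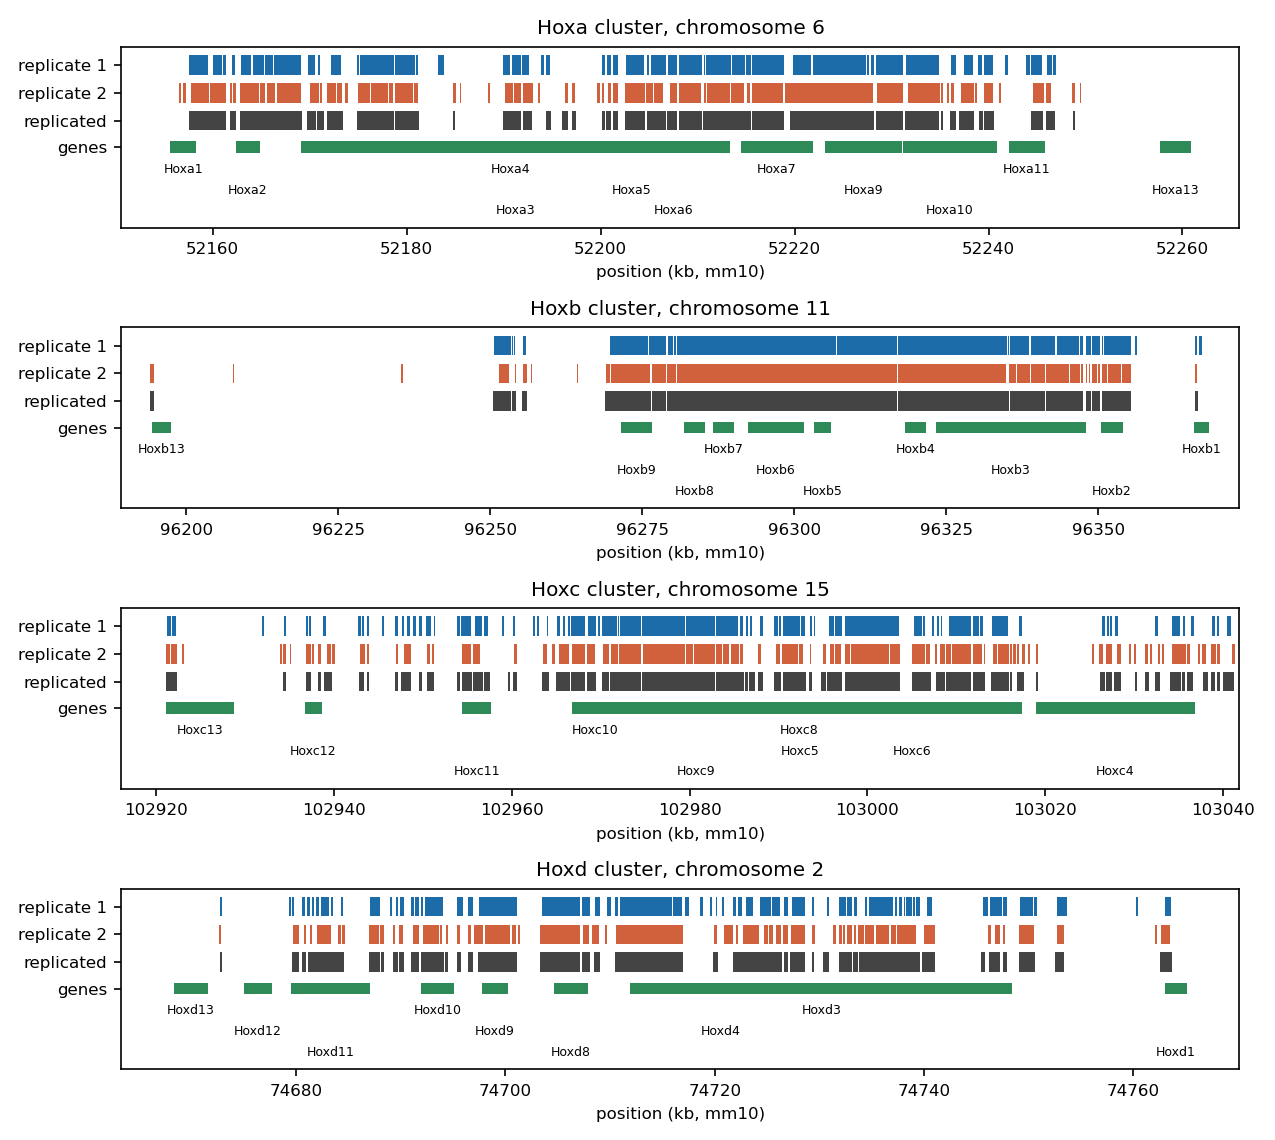
Peaks of replicate 1, replicate 2 and the replicated list (bars, to scale) over the 4 Hox clusters, with gene spans in green and positions in kb on mm10. The replicated peaks form an almost continuous block from Hoxb9 to Hoxb2 and leave Hoxa13, Hoxd12 and Hoxd13 without a promoter peak.

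Of the replicated peaks, 6379 (19.8%) lay over 10000 bp from any protein-coding start site. The strongest was 14498 bp from Chd2, which encodes a chromatin remodeller (signal 25.6, with 25.5 in replicate 1 and 17.2 in replicate 2; chromosome 7, 73556328 to 73558584), at the start of the noncoding gene 1810026B05Rik. An 11495 bp peak (18.3; chromosome 7, 79498882 to 79510376), 32520 bp from Polg, held the microRNA gene Mir9-3 and the start of its host transcript. A 9912 bp peak (17.7; chromosome 14, 64585057 to 64594968) near Kif13b held Mir124a-1 and its host, a 6121 bp peak (17.5; chromosome 2, 180890350 to 180896470) near Ythdf1 held Mir124a-3, and a 6700 bp peak (17.2; chromosome 9, 41577944 to 41584643), 389944 bp from Sorl1, held Mir125b-1. The others were nearest to A830005F24Rik (19.7), Ern1 (18.8, in an exon of Tex2), Trpv2 (18.6), Pum2 (18.5) and Cplx2 (17.5). Each of the 10 overlapped a peak in both replicates, with signals of 10.05 or more.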

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

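Peaks outside chromosomes 1 to 19 and X entered no comparison, and some carried signal. The replicated list held 14 such peaks, with a highest signal of 8.49 on an unplaced sequence assigned to chromosome 4. Chromosome Y had 2 replicated peaks, with a highest signal of 5.19, and 2 in each replicate's own list (highest signals 5.15 and 4.64). The replicate lists held 22 and 13 peaks on these sequences in all. They were noted because they lie in data the comparisons did not use, and no explanation for them was tested.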

How the results depend on the processing

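Of the alternatives, those limited to CpG-rich promoters in signal and breadth, each domain counted once, and replicated peaks that overlap both replicates were chosen after the data were seen; the others were planned. Depth is unknown and limits how far the weakest peaks can be read. No paired analysis was possible because there is 1 group. The cause of a change was not tested unless it is stated.

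An overlap of at least 50% of the shorter peak gave 48.3% and 53.3% of shared peaks in replicates 1 and 2 and a rho of 0.777, and −log10 p in place of signal also gave 0.777. A −log10 p of 5 or more in both lists gave 70.9% and 74.3%. Of the peaks that pass it, 7565 and 6207 had no partner in the other replicate's full list, fewer than over all peaks because weak peaks were left out. Genes with a promoter peak ranged from 65.8% to 66.1% with either replicate alone; they were 64.1% with a 500 bp and 65.7% with a 2500 bp window, 67.3% with the pooled list, 64.3% at −log10 p of 5 or more, 60.9% with 1 start site per gene, and 63.7% with peaks overlapping both replicates. In the same order, promoter peaks were 41.5% to 44.9%, 55.7%, 68.5%, 36.9%, 62.8%, 48.0% and 67.1% of peaks.

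Within CpG-rich promoters 0 lists stood above the other genes, against 6. The log2 odds ratio turned for pan-neuronal (-0.94), progenitor and radial glia (-0.77), Hox groups 1 to 4 (-1.12), Hox groups 5 to 9 (-0.50), cell cycle (-0.38) and housekeeping genes (-0.50), each with all members present and the 0.5 added per cell setting the sign. It passed the threshold at -3.65 for progenitor domain and -3.62 for postmitotic interneuron factors. The pooled list brought motor neuron genes (3.82) and meningeal genes (2.23) past the threshold. Erythroid genes passed it with a 500 bp window (-2.06), a 2500 bp window (-1.73), the pooled list (-1.83), no receptor genes in the background (-1.96) and either replicate alone (-1.75 to -1.73). With a replicate left out, cardiac genes ranged from -1.88 to -1.51 and lost the call without replicate 2.

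Lists above random lists in signal were 2 with −log10 p and 0 within CpG-rich promoters, against 1. Without joining, 5 lists were above and 8 below in breadth, against 8 and 4; with a replicate left out, 6 to 7 were below. Postmitotic interneuron breadth turned to 47.2 without joining and was 45.6 to 52.7 with a replicate left out, Hox groups 10 to 13 turned to 35.6 without joining, and housekeeping breadth turned to 47.5 within CpG-rich promoters. In 516 further comparisons the result stayed on its side of the threshold or, where a count or share had no test, close to its value. Of single-list values of signal and breadth, 18 passed the threshold under an alternative and 10 lost it.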

Other observations

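In this part, all patterns were picked after the results were seen, as were the gene families and the tests of peaks without a partner, the 2500 bp window, the breadth contrast and noncoding start sites. Only the tests of chromosome X and of CpG content at progenitor domain factors had their reading fixed before they were run. Families defined by symbol showed further contrasts in promoter peaks. Because CpG-rich promoters carried a peak more often, each family was set against genes of the same CpG class, rich or not, by an exact test adjusted over 14 families, in which neighbouring genes are not independent. The clustered protocadherins, cell surface proteins of neurons encoded in a single cluster, had few: 0 of 12 alpha genes (11.0 by CpG class, adjusted exact p = 1.2e-16), 0 of 22 beta genes (8.05, 0.00012) and 6 of 21 gamma genes (13.7, 4.1e-06). The alpha count took symbols of Pcdha and a number and left out Pcdhac symbols, while the gamma count took in Pcdhgc symbols. The alpha genes counted had 1 promoter peak in replicate 1 and 0 in replicate 2. Other neural surface and signalling families had more than their CpG class gave. A peak was at all 22 ephrin and Eph receptor genes (18.9 by CpG class, adjusted exact p = 0.016). It was at all 16 glutamate receptor genes with Gria, Grik or Grin symbols (11.3, 0.0012), the only glutamate receptors counted. Of 39 voltage-gated potassium channel genes 33 had a peak (25.8, 0.0027). For semaphorins, 18 of 20 were above all other genes (0.019, Fisher's exact test) but not past the threshold within the CpG class (15.2, 0.073).

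Ribosomal protein genes had a peak at 80 of 83 (75.7 by CpG class, adjusted exact p = 0.047, median signal 15.3) and proteasome genes at 38 of 40 (33.4, 0.012, median 14.5). The Hist1 histone cluster, with 94.4% CpG-rich promoters, had 43 of 54. This was above all other genes (0.022, Fisher's exact test) and below genes of the same CpG class (50.6, 8.8e-05). Families with few or no CpG-rich promoters were below their class: keratins with 4 of 53 (19.4, 5.7e-06), family 2 cytochrome P450 genes with 8 of 49 (19.1, 0.00074), beta-defensins with 0 of 42 (15.4, 6.6e-08) and bitter taste receptors with 0 of 35 (12.8, 6.5e-07). For 7090 noncoding genes, the gene's 5′ end lay over 10000 bp from any coding start site. Of these, 605 (8.53%) had a peak within 1000 bp of any start site, and 548 had one in both replicates' own lists. Other start sites of these genes were not held to that distance, and microRNA genes were counted by their annotated span. Dancr (17.2), Miat (17.0), Mirlet7i (16.5), Mir124-2hg (15.2) and Snhg8 (14.9) were among the strongest. Some strong peaks far from coding genes may be promoters of noncoding genes, a hypothesis first seen in the 10 strongest. Top-quartile distal peaks were wider than those of the bottom quartile (median 824.5 against 356 bp), so midpoints were compared, without those 10. In the top quartile 19.4% of midpoints (exact 95% interval 17.5 to 21.5) lay within 1000 bp of a noncoding start site, against 5.33% (4.28 to 6.55) in the bottom quartile. Random distal places gave at most 1.33% and 1.44%.

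Promoter signal on chromosome X was lower than on every autosome. A poorer set of promoters was tested first, since 26.9% of X genes had a CpG-rich promoter against 50.7% of autosomal non-receptor genes. Among CpG-rich genes matched on CpG ratio, the ratio of medians was still 0.667 in replicate 1 and 0.621 in replicate 2, and the higher upper bound was 0.714, below the 0.9 that this explanation would need. Fewer copies of X in pools of both sexes could lower the signal, and the mean ratio of 0.644 cannot be told apart from that. The share of male embryos is not given, and that share alone would not decide it. Signal is the strength of a peak against the control, and how far the control offsets copy number is not known here. Peaks of −log10 p under 5 were also rarer per Mb on X, at 0.131 and 0.133 of the autosomal density in the replicates. Peaks of −log10 p of 5 or more were at 0.356 and 0.369. With 1 group, no biological explanation was tested.

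Peaks in a single replicate were 28457 of 59854 in replicate 1 and 22970 of 54465 in replicate 2. At least 73.0% of them had a −log10 p under 5, against at most 18.0% of shared peaks, but overlap already fell with the same p, so this share is no separate test of weak peaks near the calling threshold, which stay open. A GC bias that differs between the libraries was argued against by median GC contents 0.054 percentage points apart. A different share of tissue around the neural tube stays open: of the genes of 8 non-neural lists with a promoter peak in a single replicate, 8 were in replicate 1 and 9 in replicate 2, so 52.9% (exact 95% interval 27.8 to 77.0) lay on the larger side, too few to decide. No biological explanation was tested.

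Promoter peaks of the progenitor domain factors were weak although 90.5% of these genes had CpG-rich promoters. A lack of CpG-rich promoters was argued against: among CpG-rich genes the 14 with a peak had a median signal percentile of 0.977. This was below the 26.4 to 73.6 that 95% of random lists gave. Genes were not matched on CpG ratio within that class, so a lower ratio among CpG-rich promoters stays open. Peaks outside a narrow window were argued against as well, since a window of 2500 bp gave 3.21, against 27.9 to 71.8. Activity in a minority of the cells pooled in this tissue may lower such signals, a hypothesis that peak lists without cell types leave untested. No biological explanation was tested, because the labels give 1 group.

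A hypothesis from the breadth values was that postmitotic interneuron factors carry broader domains than progenitor domain factors. Their median percentiles were 75.6 (19 genes) and 11.7 (15 genes), with a permutation p of 0.035. Without joining of nearby peaks the medians were 47.2 and 13.1 with a permutation p of 0.27, and with replicate 1 or 2 alone, joining kept, permutation p was 0.20 (52.7 against 10.6) or 0.51 (45.6 against 14.0). The medians lay in the same order each time, but p was under 0.05 in none of these 3 settings, so the contrast stays undecided.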
